A study of Mus musculus with 6 samples.

How the data were processed

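RNA of 6 wells of primary mouse lung fibroblasts, 3 with vehicle and 3 with purmorphamine (5um in the labels, read as 5 µM) for 24 h, was measured on Affymetrix arrays, 1 array per well. Per the labels' protocols, 100 ng of total RNA per sample was reverse transcribed from a poly(T) primer and amplified and biotinylated by in vitro transcription. Oligo, RMA and limma are named in the submitters' processing notes, and their versions are not given in the sources used here. The authors' deposited values are log2 values, 1 per probe set and array. RMA subtracts background, gives all arrays the same distribution of probe values and summarises the probes of a probe set, so a change common to all genes would not be seen, and changes of dim genes are compressed. All 6 value columns were matched to samples by their labels. Array medians lay between 6.34 and 6.39. Arrays have no read depth, and their number limits the precision: the median SE of a fitted difference was 0.07.

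Genes were named from the platform annotation that was supplied with the value table. Of 41345 probe sets, 23521 (56.9%) had 1 gene symbol, 1814 had several and 16010 had none there, and only the first kind was named. Identifiers of 23328 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which updated 0 symbols and served otherwise only to find neighbouring genes. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was used, which left 22180 genes. No filter on dim genes was applied in the main test.

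The comparison, purmorphamine minus vehicle, was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 6 arrays, without a block, and was tested two-sided with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 29 lists, and again with an estimated correlation and with fry. Groups, tests, gene lists, all alternatives but 1 and the rule for naming genes were chosen before the data were examined. By that rule, the text names the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, leaving out predicted genes and small RNAs, then the Hedgehog targets Gli1, Ptch1 and Hhip, and at most 4 members of each list with the smallest p. Some genes of the rule and the lists are not reported here. Other genes are named where a count is small or where members that did not pass are of interest, and these were chosen after their values were seen: they are mainly further members of the lists. Near-identical copies and close paralogs are marked as uncertain, since probes may bind transcripts of both.

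The alternatives were centring each array on its median, quantile normalization of gene values, a linear offset of 50, leaving out the dimmest genes (a share of 0.333), the mean of a gene's probe sets, eBayes with trend and robust, array weights, the replicate number as a block, each array left out in turn, an adjusted p under 0.1, a fold of at least 1.5, every probe set as its own test, lists without their called gene of largest change, and, chosen after seeing the data, the heat shock list without both Hspa1 copies. The steps were tested on simulated data for this comparison with 22180 genes. Of these, 89% of genes changed 2-fold and 50% of genes changed 1.41-fold were recovered. Of 142 calls 3 were false, and with no changed gene 0 were called. The simulation had far fewer changed genes than were called in the data, and its noise was independent between genes. These rates therefore need not hold for the real arrays. Python 3.11.15 and matplotlib 3.10.9 were used to read the files and draw the plots.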

Results

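Gene expression was measured with Affymetrix arrays in primary lung fibroblasts, cells enriched from digested lungs of male C57BL/6 mice aged 8 weeks and passaged at most 3 times. Cells were divided over culture wells and received vehicle or purmorphamine for 24 h, at a dose that the labels write as 5um and that is read here as 5 µM. Purmorphamine is a small molecule that activates Smoothened, the membrane protein through which Hedgehog signals reach the Gli transcription factors. There were 3 wells and 3 arrays in each of the 2 groups. The deposited table held 41345 probe sets, from which 22180 named genes were tested. Array medians lay between 6.34 and 6.39 on the log2 scale, and the median standard deviation of a gene within a group was 0.09. Across genes, which are not independent replicates, arrays of the same group correlated at 0.996 to 0.997 and arrays of different groups at 0.992 to 0.993. The first principal component, with 54.7% of the variance, separated the vehicle arrays from the purmorphamine arrays. On the second, with 13.2%, vehicle replicate 3 (-13.55) and purmorphamine replicate 3 (-9.56) lay apart from the other arrays (3.06 to 6.88). The number of arrays limits the precision, and since the labels describe cells split over wells, without saying from how many pools or mice, p-values measure only the spread between wells, which may be technical.

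The comparison of purmorphamine with vehicle asks which transcripts a Hedgehog agonist changed in lung fibroblast cultures. Of the genes of cholesterol synthesis and uptake, 15 of 16 measured fell, with squalene epoxidase Sqle at 2.76-fold lower, and all 25 measured proliferation genes fell, led by the replication helicase gene Mcm5 at 2.04-fold lower. Among unfolded protein and amino acid stress response genes 12 of 18 rose, including Ddit3, which encodes the transcription factor CHOP, by 2.26-fold. The largest falls included that of F13a1, coagulation factor XIII A, at 4.46-fold lower, and the largest rises that of Slc7a11, the cystine and glutamate antiporter, at 3.79-fold higher. Leukocyte transcripts were bright in these cultures, with vehicle means of 13.96 for Lyz2, 13.21 for Cd68, 13.08 for Fcer1g and 12.91 for Marco, against upper quartiles of 8.20 to 8.24 over the arrays. The purity of the cultures is not given in the sources used here, so all changes are those of whole cultures and are not assigned to fibroblasts or another cell type. The Hedgehog targets Gli1, Ptch1 and Hhip did not pass the test. With limma and Benjamini-Hochberg adjustment, 3181 genes changed, 14.3% of those tested, of which 1593 rose and 1588 fell. Changes were mostly small: 214 of the raised and 311 of the lowered genes moved by at least 1.5-fold, and 36 and 81 by at least 2-fold. The 3 purmorphamine values lay all above or all below the 3 vehicle values in 7582 genes, 34.2% of those tested, where chance gives 10%. With 1 array left out, and so fewer samples, 1967 to 2374 genes changed: 2034 without vehicle replicate 2, 2110 without vehicle replicate 3, 1967 without purmorphamine replicate 1 and 2065 without purmorphamine replicate 3. The number of raised genes was 2416 with a variance trend and robust fit and 1052 with every probe set tested separately.

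**Figure D1:**
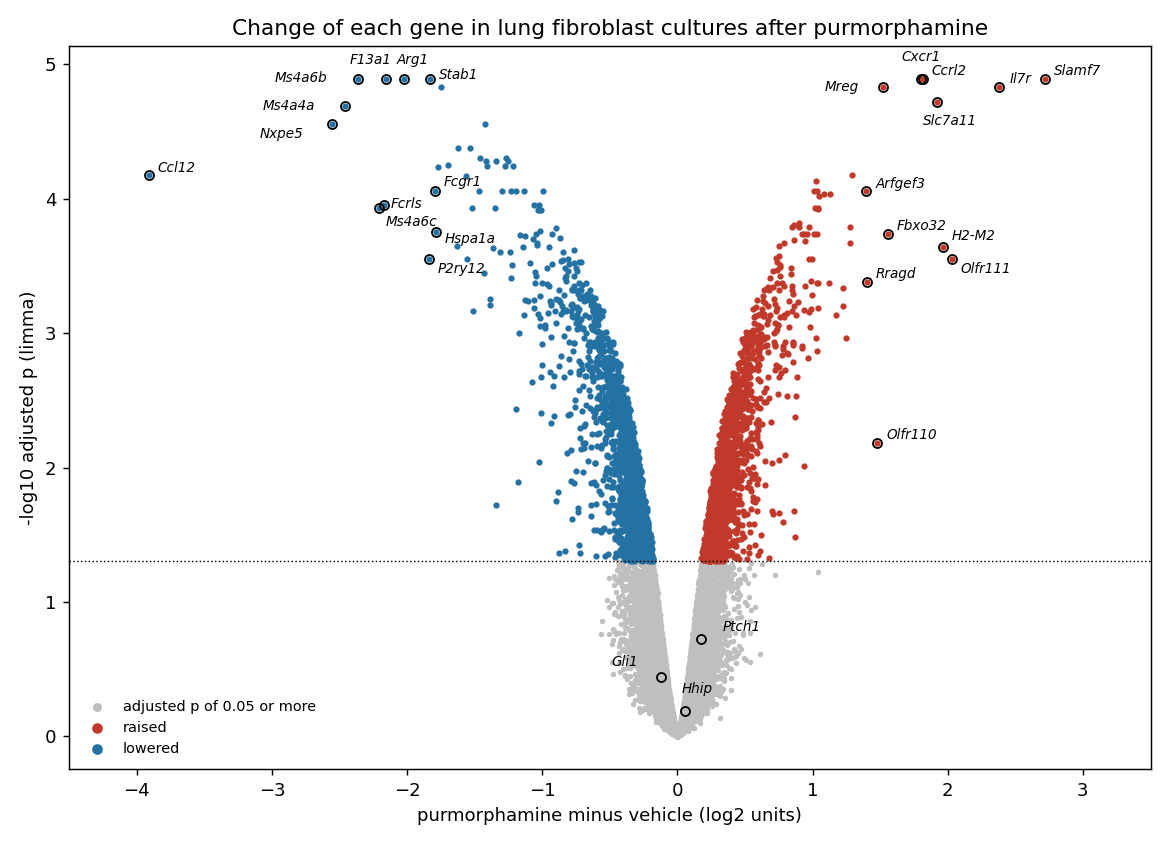
Each point is 1 of the 22180 genes, with the difference between purmorphamine and vehicle in log2 units on the horizontal axis and -log10 of limma's adjusted p on the vertical axis; red and blue points lie past an adjusted p of 0.05 (dotted line), and the circled genes are the largest rises and falls and the Hedgehog targets. Ccl12 lies farthest left at -3.91 and Slamf7 farthest right at 2.72, while Gli1, Ptch1 and Hhip lie below the line.

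The largest rises among named genes belonged to Slamf7, an immune cell surface receptor, which rose by 2.72 log2 units (SE 0.08, n = 3 per group, limma adjusted p = 1.28e-05), and Il7r, the interleukin 7 receptor alpha chain, which rose by 2.38. Slc7a11 rose by 1.92, from 10.01 ± 0.07 to 11.93 ± 0.06 (SD, n = 3). The chemokine receptor genes Cxcr1 and Ccrl2 rose by 1.82 and 1.80. The remaining large rises were those of Fbxo32, a muscle atrophy ubiquitin ligase (1.56), Mreg (1.52), Rragd, a GTPase of amino acid signalling to mTORC1 (1.40), and Arfgef3 (1.40). Olfr111 and Olfr110, which encode similar olfactory receptors and are uncertain as separate signals, rose by 2.03 and 1.48, and H2-M2, a nonclassical MHC class I gene, rose by 1.96. Adjusted p-values of these 12 rises ran from 1.28e-05 to 0.0066.

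Falls were larger. The chemokine gene Ccl12 fell by 3.91 log2 units (SE 0.18, limma adjusted p = 6.70e-05), from 8.46 ± 0.33 to 4.55 ± 0.21 (SD, n = 3). The purmorphamine mean lies under the lower quartile of every array, the lowest of which was 5.03, and may be background, so the size of this fall is not exact. Fcrls fell by 2.17, F13a1 by 2.16, the purinergic receptor gene P2ry12 by 1.84, the scavenger receptor gene Stab1 by 1.83 and the Fc receptor gene Fcgr1 by 1.79. Of the membrane-spanning Ms4a family, Ms4a4a fell by 2.46 and the close paralogs Ms4a6b and Ms4a6c, which probes may not tell apart, fell by 2.36 and 2.21. Nxpe5 fell by 2.55 and Arg1, the arginase of alternatively activated macrophages, fell by 2.03. Hspa1a fell by 1.79 beside its nearly identical copy Hspa1b, which fell by 1.77, so these are uncertain as separate signals. Alongside these genes, the leukocyte marker Itgam fell by 1.46, while Lyz2 and Ptprc, chosen after their values were seen, differed by 0.05 and 0.07 and did not pass the test.

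Among 14 measured Hedgehog target genes, 2 rose and 4 fell, and the list as a whole did not shift (camera adjusted p = 0.60, and adjusted p = 0.67 with an estimated correlation). Gli1 differed by -0.12 (95% interval -0.29 to 0.06, limma adjusted p = 0.36), Ptch1 by 0.17 (-0.004 to 0.35, adjusted p = 0.19) and Hhip by 0.06 (-0.11 to 0.23, adjusted p = 0.65). All 3 upper limits lie under a 1.5-fold rise, which is 0.58 on the log2 scale. Gli1 and Hhip were dim, at mean signals of 6.06 and 5.31, and changes of dim genes are compressed. For them the limits bound the array values and not the change of the transcript. The forkhead gene Foxf2 rose by 0.50 and the survival gene Bcl2 by 0.31. Falls were those of cyclin D1, Ccnd1 (0.56), Nrp1 (0.36), Bmp4 (0.33) and Prdm1 (0.29). Adjusted over the list alone, 4 rose and 5 fell. The alternative set test fry, which asks only whether the genes of a list move on balance in 1 direction, gave this list an adjusted p of 0.020, downward. Of 19 Hedgehog ligands, receptors and signal transducers, 3 rose and 0 fell (5 and 0 adjusted over the list alone): the co-receptors Boc (0.41) and Cdon (0.34) and Smo itself (0.28). That list shifted upward (camera adjusted p = 0.024, and adjusted p = 0.17 with an estimated correlation). Smo was not past the test without vehicle replicate 1, vehicle replicate 2, purmorphamine replicate 1 or purmorphamine replicate 2, with adjusted p from 0.061 to 0.069. Bcl2, at adjusted p = 0.049, was past it with 1 array left out only without vehicle replicate 3 (0.060 to 0.136 without each of the others), and also missed it after median centring (0.059) and with the mean of its probe sets (0.088), while Prdm1 missed it without vehicle replicate 2 (0.051).

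**Figure D2:**
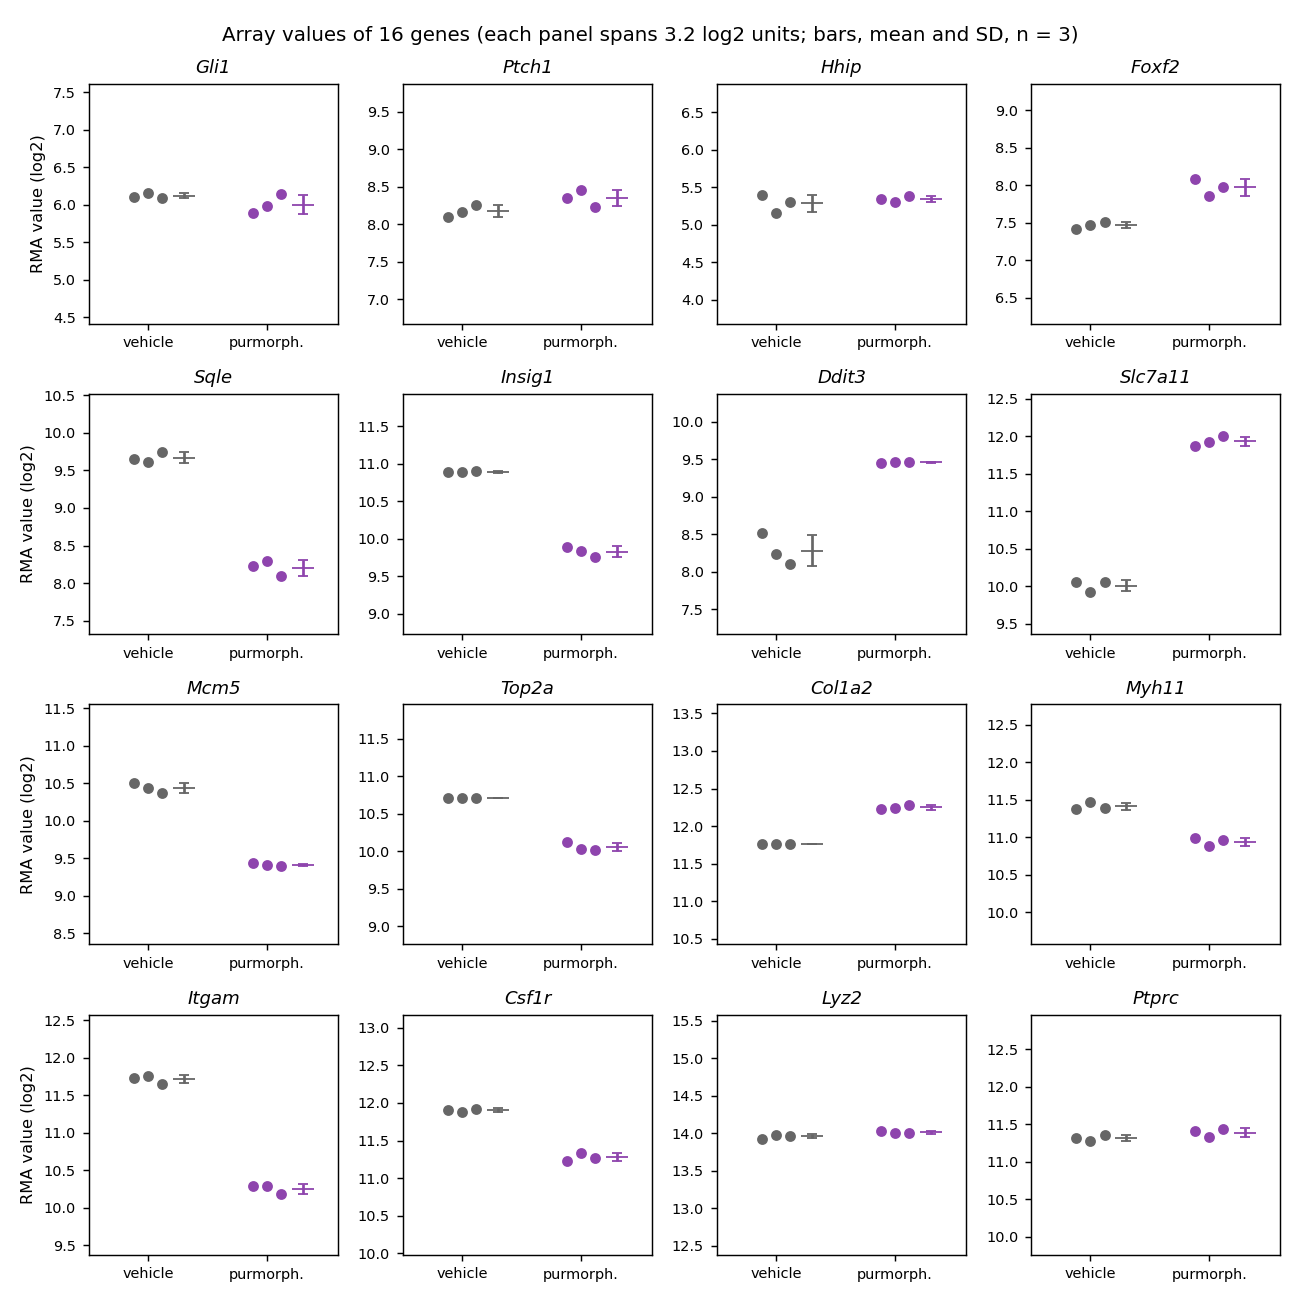
Each panel shows the RMA log2 values of 1 gene on the 3 vehicle arrays (grey) and the 3 purmorphamine arrays (purple), with the mean and SD beside them; every panel spans 3.2 log2 units. Values of Gli1, Ptch1 and Hhip overlap between groups, those of Sqle and Insig1 are lower and those of Ddit3 and Slc7a11 higher with purmorphamine, and among leukocyte markers Itgam and Csf1r are lower while Lyz2 and Ptprc differ by less than 0.08.

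Proteins of the primary cilium, where Smoothened acts, gave the list with 9 rises among 20 measured genes and 0 falls (12 and 0 adjusted over the list alone). Kif3a, a motor subunit of transport into the cilium, rose by 0.64, and the transport genes Ift122, Ift80 and Ift20 rose by 0.52, 0.47 and 0.42. The list shifted upward (camera adjusted p = 1.66e-06), and the call was lost at adjusted p = 0.079 with an estimated correlation.

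All 25 proliferation genes fell, over all genes and adjusted over the list alone, with a median of -0.58. Mcm5 fell by 1.03, Mcm2 by 0.88, Mcm6 by 0.83 and the topoisomerase gene Top2a by 0.65. The downward shift had a camera adjusted p of 9.18e-22, with adjusted p = 0.079 with an estimated correlation. Of 18 growth arrest genes 5 rose and 3 fell (6 and 3 adjusted over the list alone), with no shift of the list (camera adjusted p = 0.18). The cell cycle inhibitor gene Cdkn1b rose by 0.41, Btg1 by 0.36, Ccng2 by 0.34, Mdm2 by 0.20 and Rb1 by 0.20, although the mean of the Rb1 probe sets differed by -0.01. Mdm2 and Rb1 were not past the test with any 1 of the 6 arrays left out (limma adjusted p from 0.065 to 0.138). Cdkn2c, Gas6 and Rbl1 fell by 0.65, 0.58 and 0.51.

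Cholesterol synthesis and uptake genes had the lowest median of all lists, -0.85, and 15 of 16 fell over all genes and adjusted over the list alone. Sqle fell by 1.46 (SE 0.07, limma adjusted p = 8.84e-05, n = 3 per group), Fdps, farnesyl diphosphate synthase, by 1.23, Msmo1 by 1.21 and the sterol sensor partner Insig1 by 1.06. Srebf2, the transcription factor that drives this pathway, fell by 0.87, and Dhcr7, with -0.10, did not pass the test. The shift had a camera adjusted p of 1.47e-17, with adjusted p = 0.079 with an estimated correlation. Of 17 lysosome genes 5 rose and 0 fell (6 and 0 adjusted over the list alone): the autophagy receptor gene Sqstm1 (0.68), Gla (0.55), the calcium channel gene Mcoln1 (0.35), the cholesterol exporter gene Npc1 (0.30, against -0.02 in its dimmer probe set, and adjusted p = 0.129 with the mean of both) and Gpnmb (0.19). That list shifted upward (camera adjusted p = 0.0033, and adjusted p = 0.17 with an estimated correlation). Of 16 lipofibroblast and adipocyte genes 5 rose and 0 fell (6 and 0 adjusted over the list alone): the fatty acid binding gene Fabp4 (1.22), Cd36 (0.50), Tcf21 (0.42), Fabp5 (0.34) and Lpl (0.26). Among the 11 members not past the test were Adipoq (-0.03), Plin1 (-0.09), Plin4 (0.06), Lipe (0.02) and Pparg (0.15). These rises are therefore not read as those of a lipofibroblast or adipocyte programme. The upward shift of this list had a camera adjusted p of 0.0090, with adjusted p = 0.27 with an estimated correlation. With 1 array left out, Gpnmb missed the test in all 6 cases (adjusted p from 0.074 to 0.117), Fabp5 in 5 (0.068 to 0.094), and Mcoln1 and Lpl in 2 each (0.051 to 0.054).

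Stress response genes rose in part. The 12 rises among 18 unfolded protein and amino acid stress response genes, with 0 falls, were also 12 and 0 adjusted over the list alone, and the list had the highest median, 0.52. Ddit3 rose by 1.18 and Atf3, a transcription factor induced by stress, by 0.90. Herpud1 rose by 0.65 and Vldlr by 0.67. Among members chosen after their values were seen, Chac1 (0.88), Trib3 (0.86) and Atf4 (0.62) rose. The 6 members not past the test were Phgdh (0.16), the chaperone gene Hspa5 (0.06), Xbp1 (0.01), Sdf2l1 (-0.003), Psat1 (-0.03) and Slc7a5 (-0.03). The shift had a camera adjusted p of 1.43e-09, with adjusted p = 0.079 with an estimated correlation. Xenobiotic and oxidative stress response genes rose in 8 of 15 cases and fell in 1 (9 and 1 adjusted over the list alone), with Slc7a11 ahead of the aryl hydrocarbon receptor targets Cyp1a1 (1.04) and Cyp1b1 (0.37) and the quinone reductase gene Nqo1 (0.46), while Hmox1 fell by 0.29. The camera adjusted p was 4.00e-04, with adjusted p = 0.079 with an estimated correlation. Of 13 heat shock genes 4 fell and 1 rose (4 and 1 adjusted over the list alone): besides the Hspa1 copies, Dnajb1 fell by 0.30 and Hspb1 by 0.27, and Bag3 rose by 0.23. The downward shift had a camera adjusted p of 0.0050, with adjusted p = 0.14 with an estimated correlation. That call rested on the Hspa1 copies: without both, the 11 genes left had a camera adjusted p of 0.117. Their median was -0.10, little different from -0.12 for all 13 genes. Of the heat shock calls, those of Bag3 and Dnajb1 were lost in 5 of 6 cases with 1 array left out and that of Hspb1 in 4, with adjusted p from 0.076 to 0.114.

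Immediate early genes fell in 5 of 18 cases and rose in 2 (9 and 3 adjusted over the list alone). Klf2 fell by 1.04, Fos by 0.90, Nr4a1 by 0.49, Zfp36 by 0.48 and Myc by 0.29, and Btg2 and Jund rose by 0.44 and 0.41, the latter by 0.30 with the mean of its probe sets. The downward shift (camera adjusted p = 0.030, and adjusted p = 0.30 with an estimated correlation) was not past the threshold without vehicle replicate 1 (0.060) or purmorphamine replicate 3 (0.113). Myc missed the test in 3 of 6 cases with 1 array left out (adjusted p from 0.055 to 0.059). Bnip3, which rose by 0.47, was the 1 call among 15 hypoxia and glycolysis genes, also adjusted over the list alone, and the list did not shift (camera adjusted p = 0.18).

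Extracellular matrix genes moved unevenly. Of 22 collagen and matrix genes 8 rose and 0 fell (10 and 0 adjusted over the list alone), among them the collagens Col1a2 (0.48) and Col3a1 (0.47) and the proteoglycans Dcn (0.46) and Vcan (0.45). The upward shift had a camera adjusted p of 7.77e-04, with adjusted p = 0.28 with an estimated correlation. Of 18 matrix proteases and inhibitors 9 rose and 3 fell (10 and 4 adjusted over the list alone): Mmp12, the macrophage elastase, rose by 1.03, Mmp3 by 0.97 and the plasminogen activator gene Plat by 0.75, while Mmp9 fell by 1.14, Plau by 0.58 and Adamts5 by 0.40. That list had a camera adjusted p of 0.024, upward, with adjusted p = 0.27 with an estimated correlation. Contractile genes of myofibroblasts and smooth muscle fell in 8 of 18 cases and rose in 0 (11 and 0 adjusted over the list alone). Smooth muscle myosin Myh11 fell by 0.47, Cnn2 by 0.36, Myl9 by 0.28 and the alpha smooth muscle actin gene Acta2, chosen after its value was seen, by 0.19. The camera adjusted p was 0.0021, with adjusted p = 0.18 with an estimated correlation. Acta2 missed the test with any 1 of the 6 arrays left out (adjusted p from 0.088 to 0.099) and Myl9 in 3 of these cases (0.059 to 0.061).

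Secreted growth factor genes rose in 6 of 19 cases and fell in 0, also adjusted over the list alone: Fgf10 (0.79, against 0.45 in its dimmer probe set), Hgf (0.75), Fgf7 (0.56) and Vegfa (0.35) are known as signals from mesenchyme to epithelium or endothelium. The list shifted upward (camera adjusted p = 6.84e-04, and adjusted p = 0.079 with an estimated correlation). Of 13 BMP response genes 5 rose and 2 fell (6 and 2 adjusted over the list alone), with a camera adjusted p of 0.023, upward, and adjusted p = 0.17 with an estimated correlation. The BMP antagonist gene Grem1 rose by 0.86 and the BMP binding protein gene Bmper by 0.48, beside Hey1 (0.34), Smad6 (0.21) and Id2 (0.21), whereas Bmp2 fell by 0.46 and Id1 by 0.34. Of 16 TGF-beta response genes 1 rose and 4 fell (2 and 6 adjusted over the list alone), with no shift of the list (camera adjusted p = 0.20): Ltbp2 rose by 0.29, and Tgfbi, Tgfb3, Ccn1 and Tgfb2 fell by 0.52, 0.39, 0.37 and 0.28. Of 17 Wnt target and antagonist genes Dkk3 (0.40) and Dkk2 (0.30) rose, and 0 fell, also adjusted over the list alone (camera adjusted p = 0.12). Among these genes, Id2 and Smad6 missed the test with any 1 of the 6 arrays left out, Dkk2 and Tgfb2 in 5 of these cases and Bmp2 in 4, with adjusted p from 0.051 to 0.130.

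Inflammatory cytokine and chemokine genes rose in 9 of 21 cases and fell in 3 (10 and 3 adjusted over the list alone). Il1a rose by 1.29, the acute phase gene Saa3 by 0.72 and Cxcl12 by 0.39, while the monocyte chemokine genes Ccl7 and Ccl2 fell by 0.53 and 0.34 and Cxcl5 by 0.36. The upward shift had a camera adjusted p of 0.023, with adjusted p = 0.24 with an estimated correlation, and Cxcl5 missed the test in 5 of 6 cases with 1 array left out (adjusted p from 0.055 to 0.076). Of 16 interferon response genes 0 rose and 4 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.052): Oas2, Stat2, Oasl2 and Dhx58 fell by 0.91, 0.53, 0.48 and 0.46.

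Markers of other cell types were measured in the same cultures. Of 16 leukocyte markers 1 rose and 7 fell (3 and 7 adjusted over the list alone): besides Itgam, Coro1a fell by 0.71, the macrophage growth factor receptor gene Csf1r by 0.63 and the mannose receptor gene Mrc1 by 0.62, and the dendritic and alveolar macrophage integrin gene Itgax rose by 0.31. The downward shift had a camera adjusted p of 0.023, with adjusted p = 0.24 with an estimated correlation. Fibroblast markers did not shift (camera adjusted p = 0.62): of 15, Pdgfra (0.83) and Fbln1 (0.34) rose and S100a4, Thy1 and Col14a1 fell by 0.35, 0.32 and 0.27, with 2 and 3 also adjusted over the list alone. Of 14 endothelial markers 4 rose and 0 fell, also adjusted over the list alone: Vwf (0.50), Tie1 (0.36), Cdh5 (0.34) and Pecam1 (0.30), with a camera adjusted p of 0.0013 and adjusted p = 0.085 with an estimated correlation. Of 11 pericyte markers Rgs5 (1.22, against 0.52 in its dimmer probe set), Notch3 (0.43) and Pdgfrb (0.38) rose and Cspg4 fell by 0.31, also 3 and 1 adjusted over the list alone (camera adjusted p = 0.22). Of 15 epithelial markers Epcam rose by 0.50 and Sftpd fell by 0.23, also 1 and 1 adjusted over the list alone (camera adjusted p = 0.28). The mesothelial marker Bnc1 rose by 0.42 among 11, with 0 rises and 0 falls adjusted over the list alone (camera adjusted p = 0.58). Of 13 reference genes used for normalization 0 rose and 3 fell (1 and 3 adjusted over the list alone): Tfrc by 0.51, Gusb by 0.27 and Actb by 0.22. The reference list did not shift (camera adjusted p = 0.72), and its median of 0.02 and its mean of -0.03 differ in sign. Calls of Actb and Sftpd were lost with any 1 of the 6 arrays left out, that of Bnc1 in 5 of these cases, those of Col14a1, Cspg4 and Tie1 in 4 and that of Cdh5 in 2, with adjusted p from 0.050 to 0.125.

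**Figure D3:**
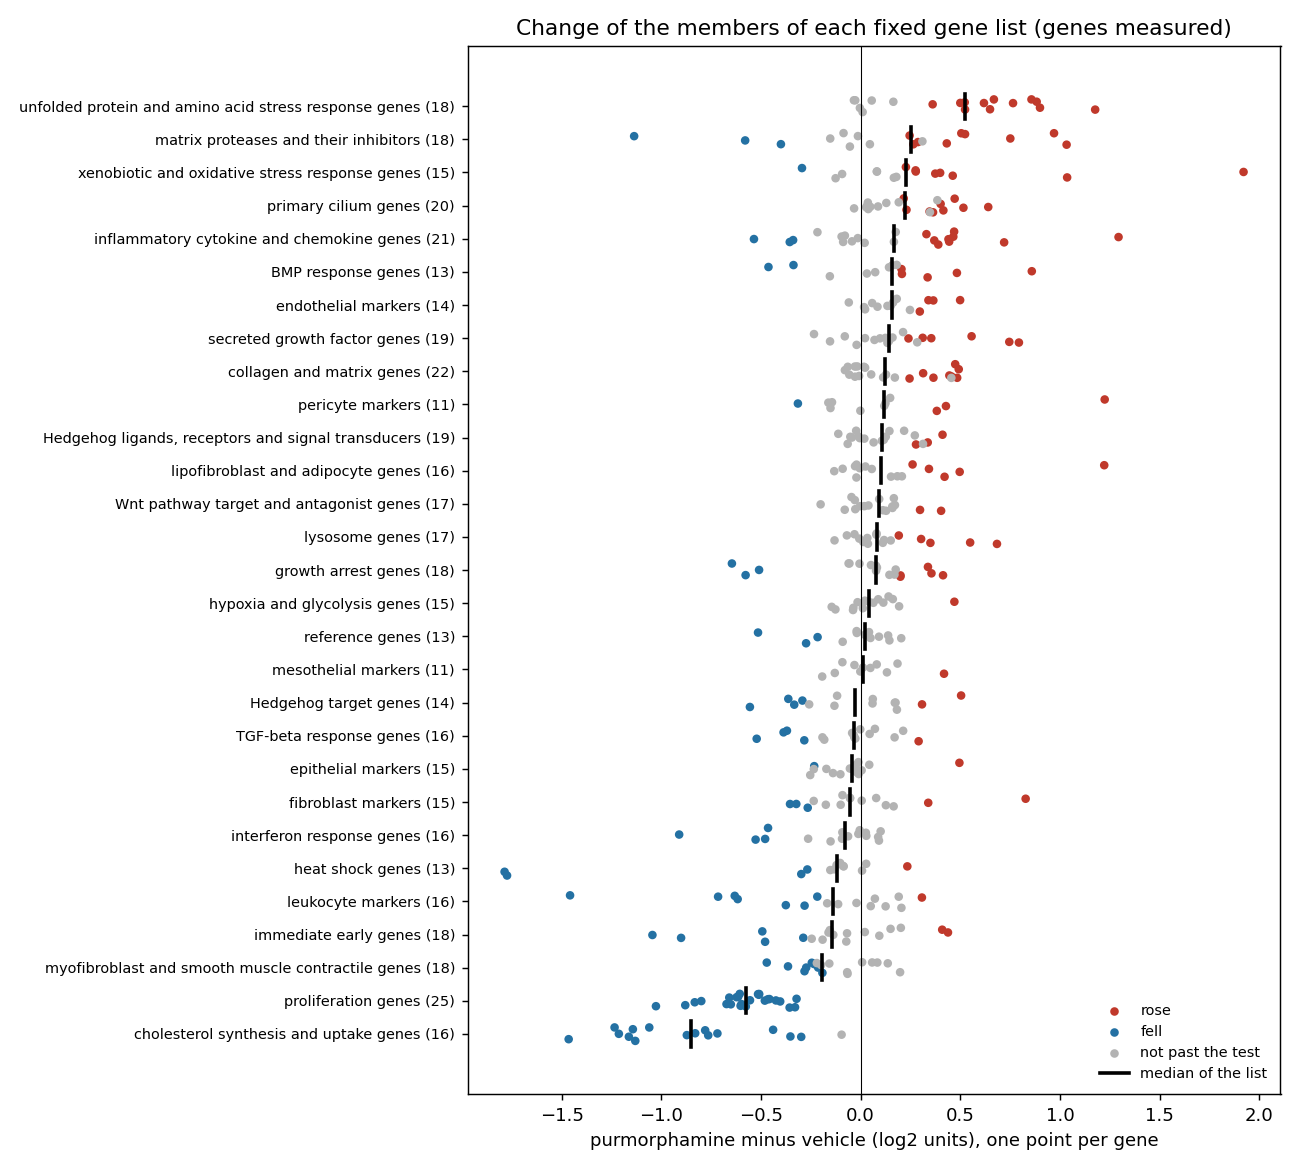
Each row is 1 of the 29 gene lists, with the number of measured genes in brackets, and each point is a gene placed at its difference between purmorphamine and vehicle in log2 units; red genes rose, blue genes fell, grey genes did not pass the test, and the black bar is the median of the list. Medians run from -0.85 for cholesterol synthesis and uptake genes to 0.52 for unfolded protein and amino acid stress response genes.

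In all, camera with a preset correlation called 18 of the 29 lists, 12 upward and 6 downward. With an estimated correlation 0 lists passed limma's camera after adjustment, 8 lay at an unadjusted p under 0.05, and fry called 25. Camera with an estimated correlation takes its degrees of freedom from the few arrays, while the preset form takes them from the genes. The camera p was larger even for lists with an estimated correlation below the preset 0.01. It went from 6.9e-05 to 0.013 for xenobiotic genes (correlation -0.025) and from 1.4e-04 to 0.014 for secreted growth factor genes (-0.046). So a lost call does not by itself show that correlated genes explain a shift. Other lists had estimated correlations well above the preset: 0.28 for collagen and matrix, 0.15 for proliferation and 0.14 for cholesterol genes. For these, correlated genes may also be part of why the p was larger, and the causes were not separated. Without the dimmest genes, a share of 0.333 of all, the Hedgehog transducer list had an adjusted p of 0.061, matrix proteases 0.064, inflammatory genes 0.063, BMP response genes 0.058 and immediate early genes 0.051. Without the called gene of largest change the Hedgehog transducer list had 0.076, inflammatory and BMP response genes 0.086 each, immediate early genes 0.105 and leukocyte markers 0.087.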

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

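The signal in probe sets that the comparison of genes does not use was examined. Of the 17824 probe sets with no single gene symbol, 377 passed limma's test over all probe sets. Of these, 210 were higher and 167 lower with purmorphamine than with vehicle. These probe sets are not named here, and no explanation was tested. Groups of 3 arrays were not searched for samples far from the others.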

How the results depend on the processing

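Alternatives to the main test were chosen before the data were examined, except the heat shock list without both Hspa1 copies (adjusted p = 0.117), which was chosen after seeing the data. The median of all genes moved from -0.01 to -0.02 after median centring and to 0.00 after quantile normalization. Counts of changed genes moved by over 1.5 times in these cases: 525 changed, 214 raised and 311 lowered genes at a fold of at least 1.5, 2416 raised with trend and robust, and 1052 raised with every probe set tested. Leaving out 1 array, and so testing fewer samples, gave 1967 to 2374 changed, 897 to 1168 raised and 1057 to 1206 lowered genes. The lowest raised counts were 957 without vehicle replicate 2, 1025 without vehicle replicate 3, 897 without purmorphamine replicate 1 and 1008 without purmorphamine replicate 3, and 1057 genes were lowered without purmorphamine replicate 3. Camera with an estimated correlation called 0 lists, and fry gave the Hedgehog target list an adjusted p of 0.020, against 0.48 to 0.99 in its other settings; fry does not compare a list with other genes. The replicate numbers share only a number: deviations of same-numbered arrays correlated at 0.11, 0.02 and 0.10, and each array correlated best with its own number, a hint from the data and not the design. As a block they gave 2432 changed genes and 17 lists, with immediate early genes at adjusted p = 0.054. Interferon response genes, at 0.052, passed in 8 of 15 settings, from 0.019 to 0.213. These settings leave out fry, where the list passed (adjusted p = 0.021), and camera with an estimated correlation, where it did not (adjusted p = 0.27). Of 178 named genes past the test, 32 were not past it without 1 array or more, with adjusted p from 0.050 to 0.138, and their changes were at most 0.46. Among these 178 genes the direction was kept except for Rb1, at adjusted p = 0.944 and -0.01 with the mean of its probe sets; its dimmer probe set lowers that mean. The dimmest genes, a share of 0.333, held 175 of the 3181 changed genes, at a median SD within groups of 0.14 against 0.06 in the brightest such share. Without them, and so with fewer genes tested, 4342 genes changed.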

Other observations

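Tests of leukocyte share, replicate spread, signal level and array scaling, and the lists of interstitial and alveolar macrophage markers, LXR targets and TFEB and TFE3 targets, were chosen only after the results of the comparison were seen, as was the search for neighbouring genes. The 4 lists chosen then were adjusted together with the fixed ones, over 33 lists. The complement genes C1qa, C1qb and C1qc, which macrophages express, fell by 1.35, 1.30 and 1.34 log2 units. Of 11 measured interstitial macrophage markers, of which 0 were in the earlier lists, 7 fell and 0 rose (camera adjusted p = 6.06e-07, and the call was lost at adjusted p = 0.067 with an estimated correlation): Dab2 fell by 0.95, Folr2 by 0.84, Pf4 by 0.66, Siglec1 by 0.66, Selenop by 0.56, Cx3cr1 by 0.55 and Cd163 by 0.37, the last lost in 4 of 6 cases with 1 array left out (adjusted p from 0.103 to 0.109). Dab2 and Selenop are also expressed by fibroblasts. Of 9 measured alveolar macrophage markers 2 rose and 1 fell, with no shift of the list (camera adjusted p = 0.32, and adjusted p = 0.59 with an estimated correlation): the lectin-like scavenger receptor gene Olr1 rose by 0.92 and Bhlhe41 by 0.86, Siglecf fell by 0.78, and Plet1 and Chil3, at vehicle means of 12.98 and 12.94, differed by 0.18 and -0.02 and did not pass the test.

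Genes that changed at least 2-fold lay next to each other more often than in shuffled orders of 22139 placed genes. There were 3 adjacent raised pairs, against a mean of 0.057 in 10000 shuffles, and 5 adjacent lowered pairs, against 0.298. A one-sided permutation test gave p = 1e-04 for each, the smallest these shuffles can give. Shuffling treats genes as independent, so neighbouring families of similar genes can give a small p by themselves. H2-M2, Olfr110 and Olfr111 were neighbours, while the flanking Olfr109 (0.15) and Olfr112 (0.18) did not pass the test. The remaining raised pair was Ly9 (1.04) with Slamf7, and the lowered pairs were F13a1 with Ly86 (-1.02), P2ry13 (-1.17) with P2ry12, the C1q genes and the Hspa1 copies. Several of these are families of similar genes, whose probes can bind transcripts of more than 1 member. Other reasons for neighbours to change together were not tested.

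F13a1, Stab1, Fcgr1 and Arg1, which macrophages express, were among the 12 largest falls, whose median was -2.17, while Slamf7 and Mmp12, which they can also express, rose by 2.72 and 1.03. A smaller share of all leukocytes in the treated wells would lower leukocyte markers together. The 16 markers had a median of -0.14 (95% bootstrap interval over the markers and not the wells, -0.40 to 0.07), and the 11 with a signal under 12 had a median of -0.22. Both lie above -1.08, the falls' median divided by 2, but that bar comes from the largest falls of the same data, so this says little. The markers did not fall together: they ran from -1.46 to 0.31, with 7 falls and 1 rise. That spread argues against a smaller leukocyte share as the whole cause. A loss of interstitial macrophages with alveolar macrophages kept stays open: 6 of the 8 brighter interstitial markers fell, but their median was -0.61 and Mertk differed by -0.02. It cannot be told apart from a change of expression within macrophages, since the design holds no cell counts. An effect of purmorphamine on macrophages was not tested separately.

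Gli1, Ptch1 and Hhip did not pass the test with a Hedgehog agonist. For the array values, a spread between wells too wide to show a 1.5-fold rise is excluded by the 95% limits, the highest of which was 0.35, under 0.58. Signals too low to report a change may still be part of the cause: the genes lay at percentiles 34.6, 66.7 and 21.4 of mean signal, and 23 of the 4032 genes within 0.5 of the Gli1 signal were called at a fold of at least 1.5. For Gli1 and Hhip this cannot be told apart from an unchanged transcript, since no sample with known induction is among the arrays. A weak response of these cells at 24 h is a biological explanation that was not tested.

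Cholesterol synthesis genes fell, with a median of -0.85. The list's median lay -0.86 from that of 7105 genes of like signal (95% bootstrap interval over the list's genes and not the wells, -1.15 to -0.62), so those genes did not fall with it. This is no test of a scaling factor between the groups, since RMA gives all arrays the same distribution of probe values. A smaller share of all leukocytes is argued against by the marker median of -0.14, whose interval ends above -0.43, the list's median divided by 2. That interval is over genes and not wells, and the bar was set after the values were seen. The interstitial macrophage markers had a median of -0.55 and the alveolar ones 0.16. A smaller share of interstitial macrophages is therefore not argued against here. That sterol excess sensed by LXR goes with the fall is a hypothesis that stays open: 3 of 9 LXR target genes rose, Mylip by 0.87, Abca1 by 0.60 and Abcg1 by 0.53, and Srebf1 differed by -0.09. Their median of 0.13 lay between the values set for and against it, and the list's call (camera adjusted p = 0.023) was lost at adjusted p = 0.22 with an estimated correlation. A direct effect of the treatment on sterol metabolism was not tested separately.

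With Sqstm1, Mcoln1 and Rragd raised, a wider rise of target genes of TFEB and TFE3, transcription factors of lysosome and autophagy genes, was put forward as a hypothesis and tested on 12 further targets. Of these 9 rose and 0 fell, with a median of 0.30 (camera adjusted p = 9.33e-06, and the call was lost at adjusted p = 0.067 with an estimated correlation). Gabarapl1 rose by 0.58 and the folliculin partner gene Fnip1 by 0.55. Of the 17 fixed lysosome genes, which include known targets, 12 did not pass the test and the median was 0.08, with Ctsd at 0.04, Lamp1 at 0.03 and Neu1 at -0.13, and Tfeb itself differed by -0.03. Activity of these factors was not measured and stays open, and other regulators share these targets.

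The 10 splits of the 6 arrays into groups of 3 are too few for a share under 0.05. The real split had 3181 changed genes, 1593 raised and 1588 lowered. It was the 1 split with as many changed genes and the 1 with as many in either direction. In each of the others limma called 0 genes, with 493 to 897 genes at an unadjusted p under 0.05. Those splits mix vehicle and purmorphamine arrays in both groups. The treatment difference then widens the spread within groups, so their counts do not measure what chance gives. The real split called 18 lists and was the 1 with as many, against at most 5 in the others. For the Hedgehog target list its camera p of 0.558 was matched or passed by the p of others in 3 of the 10 splits, itself included, and the lowest other was 0.304.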
